A study of Mus musculus with 18 samples.

How the data were processed

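The study recorded single dorsal root ganglion neurons of male mice in culture and sequenced the cytoplasm of each. Per the labels' protocols, ganglia were digested with collagenase and papain, neurons were kept on laminin with serum and nerve growth factors, and recordings were made 24 h after plating. Soma indentation reached up to 11 µm at a holding potential of −70 mV. RNA was purified from the aspirated cytoplasm, amplified with SMART-Seq v4, which does not mark the strand, and made into Nextera XT libraries read as 150 base pairs from both ends. Per the submitters' processing notes, bcl2fastq 2.17.1.14, FastQC 0.11.5, cutadapt 1.9.1, STAR 2.5.2a, R 3.6.1 and edgeR 3.22.5 were named with the build mm10; their roles and order were not given. The counter, its strand setting and the annotation release are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart.

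The authors deposited a table of whole-number counts per gene and a table of TPM (transcripts per 1e6), each with 17 of the 18 labelled cells. No column of per-sample values was left unused. Both tables list 15933 genes, of which 184 are at 0 in every cell. The deposited TPM values equalled the count divided by the genomic span of the gene, introns included, to within 0.508% for 99% of the values checked, scaled to a fixed total over the listed genes. This understates long genes, so counts were used for the main tests. Of the gene IDs, 15927 were found in GENCODE M21, all with the same start and end. The symbols that name 2 IDs numbered 7. Totals per cell ran from 5826652 to 23199560 counts. No pair of cells of the same age agreed within sampling noise (lowest chi-square per degree of freedom 406). PCR reads carry no molecular identifiers, so intervals and floors cover counting error only.

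Each cell was assigned to its age by its title. The labels name no animal or culture. Cells of different postnatal days were taken as separate replicates on the assumption that they came from different animals, which no label states, and cells of the same day may share an animal. Counts were summed by postnatal day within an age, giving juvenile days 28 (3 cells), 29 (1), 30 (3) and 31 (1) and adult days 85 (1), 90 (1), 94 (1), 102 (3) and 113 (3). Whether neighbouring days share an animal is not stated, and the p-values of genes compared between ages measure the spread between days.

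Day sums were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr defaults (minimum count 10, minimum total 15), TMM factors, robust dispersions, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken from its F statistic. Of 28 gene lists fixed before the data were examined, the 24 with at least 5 tested members were compared with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). Genes were related to log2 current per cell with limma voom, age as covariate and the day as a block, where the estimated correlation within a day was −0.100. Currents, depth and genes detected were compared over day means with two-sided exact permutation tests in SciPy 1.17.1, whose smallest possible p is 0.0159. Detection means 10 CPM or more unless stated. Ratios with 1 to 3 counts in an age have exact 95% intervals, and an age without counts was set to a floor of 3 counts over its cells.

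The text names the 6 smallest p-values in each direction, since none passed, among genes with at least 10 counts in 3 day sums of the higher age, leaving out predicted genes and pseudogenes; list members that passed over all genes or adjusted over the list alone, with 4 others for each list past the test and 1 for each other list; a fixed set of touch and pain neuron genes; and for current the 6 smallest p-values per direction that passed. Nefl, Nefm, S100b, Sox10, Plp1 and Sparc are given as counts of cells only, and were chosen after their values were seen.

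Alternatives were library totals or DESeq2 size factors for scaling, no filter or a stricter one, DESeq2 1.42.0, limma voom with quality weights, merged neighbouring days, cells as replicates with and without a replicate block, day means of log2(CPM + 1), TPM with pseudocounts of 1 and 0.1, and leaving out each day or cell. Regroupings of the days were fitted with edgeR, limma voom and camera; DESeq2 had been planned there too and was dropped before any result because of its run time. The fits were tested on simulated data: counts for the 7390 tested genes, drawn with the observed means, library sizes and dispersions (common dispersion 3.45), with 200 genes changed. At this spread edgeR's quasi-likelihood test recovered 0% of the genes changed 2-fold, 2% of those changed 4-fold, 8% of those changed 16-fold and 28% of those changed 64-fold, and called 0.0293% of the unchanged genes. DESeq2 recovered 56% of the genes changed 64-fold and called 2.87% of the unchanged genes. For current, 4234 genes were simulated with each cell drawn independently, so with no effect of day. Of the genes with a change of 2 on the log2 scale per doubling, 58% were recovered. Of the unchanged genes 0.694% were called, and 8.06% had an unadjusted p under 0.05. Raising the oxidative phosphorylation list 2-fold was found by camera in 12 of 20 simulated data sets. Genes were drawn independently there, whereas the estimated correlation within that list in the data was 0.223. The rate may therefore not hold for the data.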

Results

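Single neurons of the mouse dorsal root ganglia, which hold the cell bodies of touch, body-position and pain fibres, were recorded in culture by whole-cell patch clamp. The cytoplasm of each was then drawn into the pipette and its RNA sequenced. All cells came from male C57BL/6J mice, fired action potentials of the mechanoreceptor type, and answered indentation of the soma with a rapidly adapting mechanically activated current, the fast-decaying inward current typical of touch neurons. The labels describe 9 juvenile cells, taken at postnatal days 28 to 31, and 9 adult cells, taken at postnatal days 85 to 113. Counts of 8 juvenile and 9 adult cells were compared, and juvenile cell 3 was not analysed here. Total counts ran from 5826652 in juvenile cell 1 to 23199560 in juvenile cell 4 among the juvenile cells, and from 13151892 in adult cell 9 to 19836715 in adult cell 1 among the adult cells. No label names an animal, so counts of cells taken at the same postnatal day were summed, which gave 4 juvenile and 5 adult day sums. The p-values of genes compared between ages, and of day means, measure the spread between these days. Those of gene lists compare a list with the other genes, and those for current rest on single cells. Levels below are means ± SD over the day sums in CPM (counts per 1e6 normalised counts), with n = 4 juvenile and n = 5 adult days, unless cells are named.

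The first question was which kind of neuron had been sampled at each age. Per the labels, the action potential categories given match common marker genes in the RNA, so marker levels are not independent of how the cells were sorted. Transcripts of the neurofilament chains Nefl, Nefm and Nefh, the scaffold of thick myelinated axons, and of the calcium-binding protein S100b reached 10 CPM or more in 8 of 8 juvenile and 9 of 9 adult cells. Nefh stood at 4277 ± 2566 CPM in juvenile and 3982 ± 1728 CPM in adult days, a log2 fold change of −0.10 ± 0.38 (SE) that turned positive, to 0.44, with DESeq2 size factors. Piezo2, the channel that carries rapidly adapting current in touch neurons (ENSMUSG00000041482, chromosome 18, 63010213 to 63387183 on mm10), was found in 8 of 8 juvenile and 9 of 9 adult cells at that limit. Its level was 300.4 ± 81.2 CPM in juvenile and 645 ± 509 CPM in adult days, a log2 fold change of 1.10 ± 0.66 (SE) with an edgeR adjusted p = 1.00, which ranged from 0.46 to 1.31 when each day was left out. Adult cell 8 held 2185 CPM of Piezo2 and juvenile cell 9 held 33.2 CPM, the highest and lowest of the 17 cells. The related channel Piezo1 reached 10 CPM in 1 adult cell and in no juvenile cell. Tmem63b, a stretch-gated channel, reached 10 CPM in 5 of 8 juvenile and 5 of 9 adult cells. Tmem150c and Tmem120a, also of the fixed set, were found in fewer adult cells. Tmem150c reached 10 CPM in 5 of 8 juvenile and 2 of 9 adult cells, and Tmem120a in 6 of 8 and 1 of 9. Their log2 fold changes were −0.50 ± 2.31 (SE) and −2.56 ± 2.40 (SE), and neither passed. When each day was left out they ranged from −1.58 to 0.98 for Tmem150c and from −9.61 to −0.67 for Tmem120a.

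Receptors that sort touch neurons into classes varied from cell to cell within each age. Ntrk2, the receptor for BDNF and NT-4, reached 10 CPM in 4 of 8 juvenile and 7 of 9 adult cells and averaged 193 ± 213 against 759.8 ± 948 CPM. Ntrk3, the NT-3 receptor, reached it in 8 of 8 juvenile and 4 of 9 adult cells, with 702 ± 1016 CPM in juvenile days. Ret, the signalling receptor for GDNF, reached it in 6 of 8 juvenile and 5 of 9 adult cells, at 457 ± 524 against 112 ± 96.1 CPM. The log2 fold changes were 1.98 ± 1.68 (SE), −1.93 ± 1.35 (SE) and −2.02 ± 1.29 (SE), and none passed the test. When each day was left out they ranged from 0.95 to 2.86 for Ntrk2, from −3.94 to −0.09 for Ntrk3 and from −2.51 to −0.56 for Ret. Calb1, which encodes the calcium buffer calbindin, reached 10 CPM in 3 juvenile cells and no adult cell, with 9943 juvenile against 3 adult counts. That ratio of 4036 has a 95% counting interval of 1381 to 19576, and the gene was too rarely detected to be tested. It rests mainly on juvenile cell 2, the cell with the most genes detected, which held 377 CPM of Calb1. Juvenile cells 4 and 6 held 69.2 and 25.5 CPM. Pvalb, a marker of muscle-spindle afferents, reached 10 CPM in 1 juvenile cell, also juvenile cell 2. Of the nociceptor list, 8 genes were tested, 5 higher and 3 lower in adult. Calca, which encodes the neuropeptide CGRP, reached 10 CPM in no juvenile and 1 adult cell, and Th, the marker of low-threshold C fibres, in none of the 17. Calcb, the paralogue of Calca that encodes the beta form of CGRP, reached 10 CPM in 4 of 8 juvenile and 5 of 9 adult cells, with 1259 ± 1169 CPM in adult days. The Calcb log2 fold change of 6.39 ± 2.35 (SE) had an edgeR adjusted p = 1.00 and ranged from 5.97 to 8.67 when each day was left out. Stoml3, Scn10a, Trpv1 and Mrgprd were not analysed here.

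**Figure D1:**
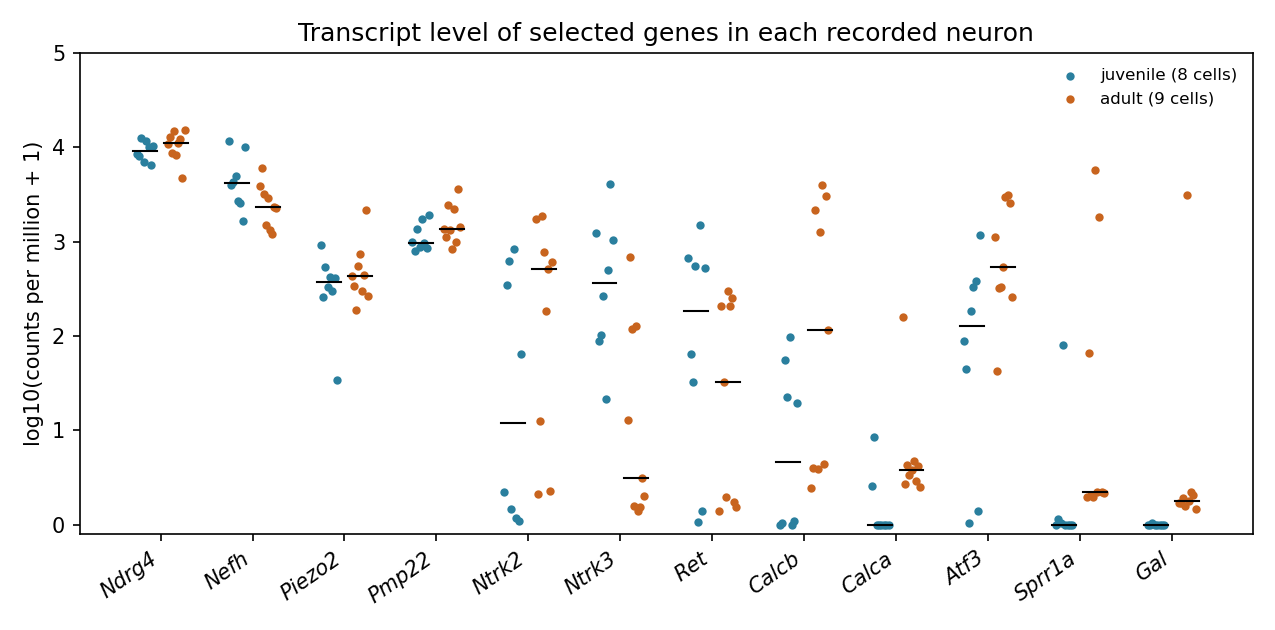
Level of 12 genes in each of the 8 juvenile and 9 adult neurons, as log10 of CPM plus 1. Points are cells and black bars the median of each age. Ndrg4, Nefh, Piezo2 and Pmp22 were present in every cell, whereas Ntrk2, Ret, Calcb and Sprr1a were high in some cells and near 0 in others of the same age, as was Ntrk3 in adult cells.

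The main comparison asked which genes differ between juvenile and adult mechanoreceptors. Among genes higher in adult neurons, the smallest p-value belonged to Ndrg4, a cytoplasmic protein abundant in neurons (ENSMUSG00000036564, chromosome 8, 95676980 to 95715119). It averaged 8419 ± 1147 CPM in juvenile and 13037 ± 2033 CPM in adult days, a log2 fold change of 0.63 ± 0.15 (SE) with an edgeR adjusted p = 0.423. Ttc9 (chromosome 12, 81631249 to 81667557) averaged 527 ± 103 against 1505 ± 584 CPM. Hspa5, the main chaperone of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), averaged 446 ± 267 against 1678 ± 967 CPM. The ubiquitin ligase Rnf11 (chromosome 4, 109451098 to 109484728) averaged 204 ± 89.1 against 808 ± 213 CPM, and the growth factor Fgf1 (chromosome 18, 38838673 to 38929472) 917 ± 478 against 2371 ± 817 CPM. Their log2 fold changes lay between 1.37 for Fgf1 and 1.99 for Rnf11. Galanin, Gal, an injury-induced neuropeptide, held 1 count in all juvenile cells together and 43730 in adult cells, of which 43624 came from adult cell 5.

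Among genes lower in adult neurons, the smallest p-values went to transcripts that were present in juvenile days and close to 0 in adult days. Nelfb, a subunit of the negative elongation factor of RNA polymerase II (chromosome 2, 25199712 to 25211489), averaged 146 ± 117 CPM in juvenile and 0.170 ± 0.105 CPM in adult days, and reached 10 CPM in 6 of 8 juvenile and 0 of 9 adult cells. The ubiquilin gene Ubqln4 (chromosome 3, 88553758 to 88569725) and the F-box gene Fbxo27 (chromosome 7, 28692849 to 28699338) each reached 10 CPM in 5 of 8 juvenile and 0 of 9 adult cells, at means of 127 and 118 CPM in juvenile days. Numa1, a spindle-pole and nuclear protein (chromosome 7, 101934111 to 102014964), reached 10 CPM in 3 juvenile and 0 adult cells. The zinc transporter Slc39a5 (chromosome 10, 128395931 to 128401229) and the glutamate transporter Slc1a6 (chromosome 10, 78780496 to 78814765) had no adult count. Against a floor of 3 counts over the adult group they were at least 205-fold and at least 234-fold lower in adult cells, but they reached 10 CPM in only 1 and 2 juvenile cells.

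None of the 7390 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 154 genes, 53 higher and 101 lower in adult. Evenly spread p-values would give 369.5 genes, but other splits of the day sums gave a median of 122. At least 154 genes were reached by 34 of 100 splits, the real grouping included. Other tools on the same day sums called more: DESeq2 1323 genes (82 higher, 1241 lower), limma voom with quality weights 122 (13 higher, 109 lower) and edgeR's likelihood ratio test 53 (1 higher, 52 lower). With the cells as observations, limma voom with the day as a block called 14 genes (2 higher, 12 lower) and edgeR's quasi-likelihood test 0. The main test itself called 48 genes with a stricter filter and 840 with neighbouring days merged, which bears on the count of 0 since neighbouring days may share an animal. The merge joined juvenile day 28 with 29 and 30 with 31, and left the adult days as they were. That gave 2 juvenile sums, each of more cells than any adult sum, so the 840 also come from a less even design.

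Gene lists fixed before the data were examined were compared next. The median log2 fold change of all tested genes was 0.41 with TMM factors, −0.01 with library totals and 0.72 with DESeq2 size factors, so list medians are given less that of all genes. Of 24 lists tested with camera at a preset correlation of 0.01, 3 passed, each in the direction of higher levels in adult, and no member of them passed over all genes. The number that passed ranged from 0 to 9 when each day was left out, and was 0 with day means of log2(CPM + 1). The axon injury and regeneration list had 16 of 22 members higher in adult (adjusted p = 0.0351). Its median lay 0.48 above that of all genes, but 0.04 below it with DESeq2 size factors, a difference of −0.04. With an estimated correlation its adjusted p = 0.801. Besides Gal it holds Atf3, a transcription factor induced by nerve injury, at 273 ± 251 against 1278 ± 1137 CPM. It also holds Rgs4, a brake on G-protein signalling, at 598 ± 583 against 1937 ± 1216 CPM. Sprr1a, a regeneration-associated protein of the list, stood at 5.47 ± 10.9 against 563 ± 841 CPM. Adult days 102 and 113 held 1939 and 804 CPM of Sprr1a and the other adult days 1.15 to 68.4 CPM. Its log2 fold change ranged from 5.25 to 13.57 when each day was left out. Of the members of the list, 1, Gal, passed when adjusted over the list alone (edgeR adjusted p = 0.0415). That call rests on adult cell 5, with 3137 CPM of Gal against 0.456 to 1.20 CPM in the other adult cells. Without adult day 102 the log2 fold change of Gal was 6.53, from 6 to 18 counts per adult cell against 1 juvenile count. Whether such low counts are expression or reads of adult cell 5 is left open below. The ubiquitin, proteasome and autophagy list had 35 of 40 members higher in adult (adjusted p = 0.0351) and a median 0.26 above that of all genes. With an estimated correlation its adjusted p = 0.801. Examples were the autophagy receptor Sqstm1, at 1659 ± 747 against 3178 ± 1853 CPM, and the proteasome ATPase Psmc4, at 237 ± 81.9 against 497 ± 239.6 CPM. The list of nuclear-encoded oxidative phosphorylation genes had 51 of 64 members higher (adjusted p = 0.0274). Its median did not exceed that of all genes, with a difference of 0.00 (−0.003), but lay 0.13 above it with DESeq2 size factors and 0.44 above it with day means of log2(CPM + 1). With an estimated correlation its adjusted p = 0.801. Examples were Atp5d, a subunit of ATP synthase, at 784 ± 275 against 1509 ± 1189 CPM, and Ndufs8, a subunit of complex I, at 117 ± 95.3 against 355 ± 89.5 CPM. Adult day 90 held 3626 CPM of Atp5d and the other adult days 805 to 1112 CPM, and its log2 fold change turned to −0.10 with day means of log2(CPM + 1). No member of the last 2 lists passed when adjusted over the list alone. When juvenile cells 2 and 4, the pair with the most genes detected, were left out after seeing the data, 0 lists passed.

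**Figure D2:**
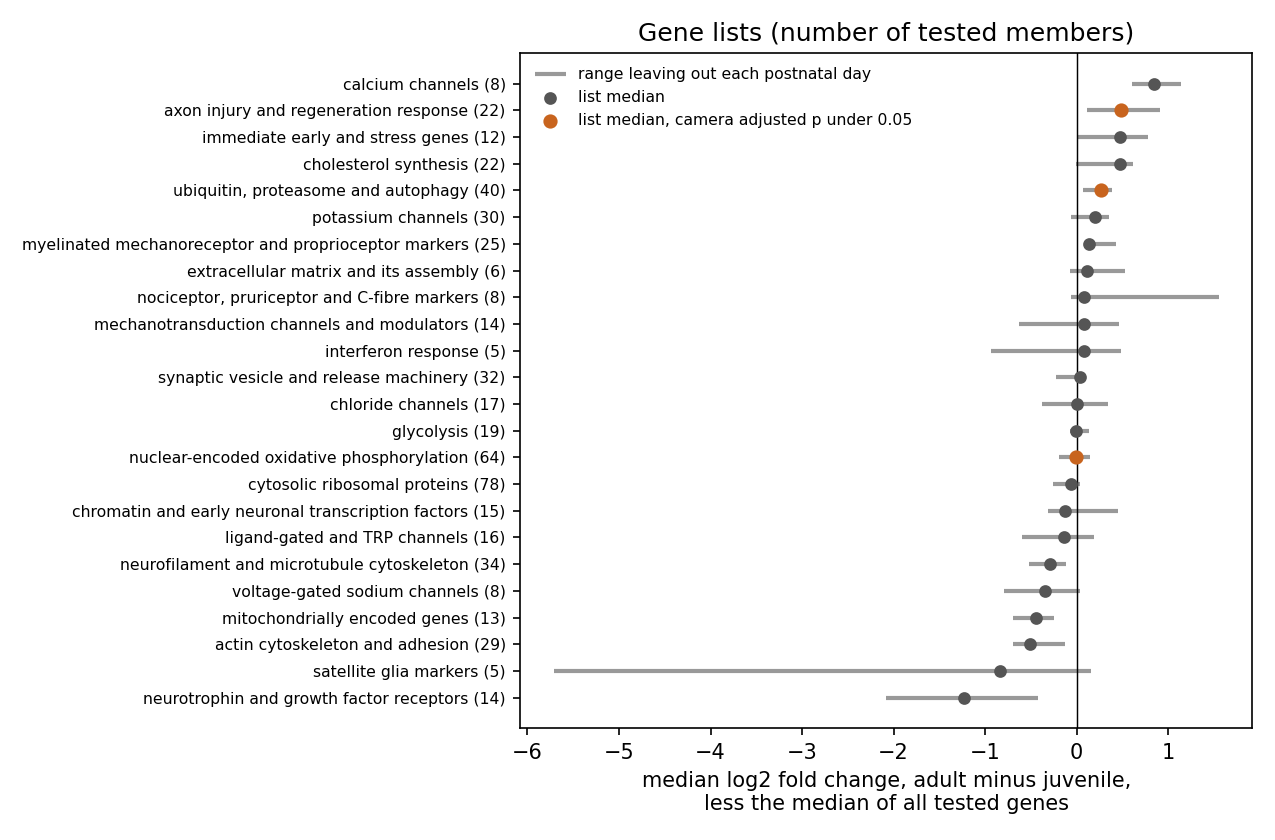
Median log2 fold change, adult minus juvenile, of 24 gene lists, less the median of all tested genes. Dots are list medians, orange for the 3 lists past the camera test, and grey bars span the values when each postnatal day is left out in turn. The oxidative phosphorylation list lies at 0 although it passed.

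The other 21 lists did not pass. The mechanotransduction list had 8 of 14 tested members higher in adult and 6 lower, and its median lay above 0 but its mean below. Of its members, 1, Pcdh15, a tip-link cadherin of hair cells, passed when adjusted over the list alone (edgeR adjusted p = 0.0155), and 0 over all genes. Pcdh15 averaged 17.1 ± 5.45 CPM in juvenile days but reached 10 CPM in only 4 juvenile cells, at 11.8 to 103 CPM, and in no adult cell. Juvenile cells 4, 6, 8 and 9 held 0 CPM of it. The gene had 2 adult against 2510 juvenile counts. That ratio of 1528 has a 95% counting interval of 423 to 12627. The list of myelinated mechanoreceptor and proprioceptor markers had 18 of 25 members higher (adjusted p = 0.155). Calcium channels had 7 of 8 higher (adjusted p = 0.155), among them the accessory subunit Cacnb3 at 360.3 ± 65.9 against 1115 ± 1207 CPM. Adult day 90 held 3176 CPM of Cacnb3, and without it the log2 fold change went from 1.63 to 0.71. Potassium channels had 21 of 30 higher and sodium channels 5 of 8. Neurotrophin and growth factor receptors had 8 of 14 lower, with a median 1.23 below that of all genes, a difference of −1.23 that ranged from −2.08 to −0.42 when each day was left out. Synaptic vesicle genes had 22 of 32 higher, including Vamp2 at 1234 ± 677 against 2784 ± 837 CPM. Glycolysis had 14 of 19 higher, led by Aldoa at 4968 ± 999 against 7794 ± 1536 CPM. In the immediate early and stress list, 1 of 12 members, Hspa5, passed when adjusted over the list alone (edgeR adjusted p = 0.0365).

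Marker transcripts of other cell types were mostly uneven between cells. Apoe, abundant in satellite glia, reached 10 CPM in 2 of 8 juvenile and 0 of 9 adult cells, with 3443 CPM in juvenile cell 9 and 781 CPM in juvenile cell 2. It passed when adjusted over the satellite glia list alone (edgeR adjusted p = 0.00469) but not over all genes (adjusted p = 0.423). Of the satellite glia list, 2 tested genes were higher and 3 lower in adult. Its median less that of all genes was −0.84, and ranged from −5.71 without juvenile day 31, where the list passed as lower (camera adjusted p = 0.0138), to 0.16 without adult day 102. Of the Schwann cell and myelin list all 4 tested genes were higher. The glial genes Sox10, Plp1 and Sparc, picked after their values were seen, reached 10 CPM in 3 of 8 juvenile cells each and in no adult cell. Rgs5, a pericyte gene, reached 10 CPM in 2 of 8 juvenile and 8 of 9 adult cells, at 182 ± 364 against 1909 ± 1602 CPM, with a log2 fold change of 3.39 ± 2.60 (SE) that did not pass and ranged from 2.79 to 12.02 when each day was left out. Pmp22, a myelin protein gene, was found in every cell, at 1027 ± 361 against 2094 ± 757 CPM. In adult cells Pmp22 stood at 840 to 3650 CPM, while Apoe was at most 3.65 CPM. Whether Pmp22 and Rgs5 came from the neuron itself or from other cells was not tested.

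A further comparison concerned the recorded current itself. Rapidly adapting currents ran from 0.491 to 22.8 nA in the 8 juvenile cells and from 0.643 to 10.1 nA in the 9 adult cells. The day means of log2 current were 1.25 ± 1.96 in juvenile (n = 4) and 0.909 ± 1.10 in adult days (n = 5), a difference of −0.34 that did not pass a two-sided exact permutation test (p = 0.746). Without juvenile day 28 the difference was 0.586.

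Transcripts were then set against the current of the same cell, with age in the model. Piezo2 changed by −0.12 on the log2 scale per doubling of current (limma adjusted p = 0.887). Of 4234 genes, 70 passed, all of them lower in cells with larger currents. On simulated data the same fit called 0.694% of unchanged genes. Cells were drawn independently there, with no effect of day, so that rate does not cover differences shared by cells of the same day. The 6 smallest p-values belonged to Mrps17, a mitochondrial ribosomal protein, Tox4, a chromatin protein, the ubiquitin-conjugating enzyme Ube2d1, the glycosyltransferase B3galnt1, the small GTPase Arf6 and the kinase Nek1. Mrps17 fell by 2.04 on the log2 scale per doubling of current (limma adjusted p = 1.09e-05), and Arf6 fell by 1.96 (limma adjusted p = 7.23e-05). Mrps17 averaged 0.206 ± 0.181 CPM over the 3 cells of juvenile day 28, whose currents were 10.0, 19.7 and 22.8 nA, and 149.9 ± 164 CPM over the other 14 cells. Arf6 averaged 0.135 ± 0.0377 CPM in those 3 cells and 243 ± 393 CPM in the other 14. Mrps17 was also under 1 CPM in adult cells 4, 5 and 7, and Arf6 in adult cells 4 and 9. Without day 28 no gene passed, and edgeR on the day sums called 0. With the number of detected genes as a covariate, a choice made after seeing the data, 14 genes passed, 12 of them among the 70.

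**Figure D3:**
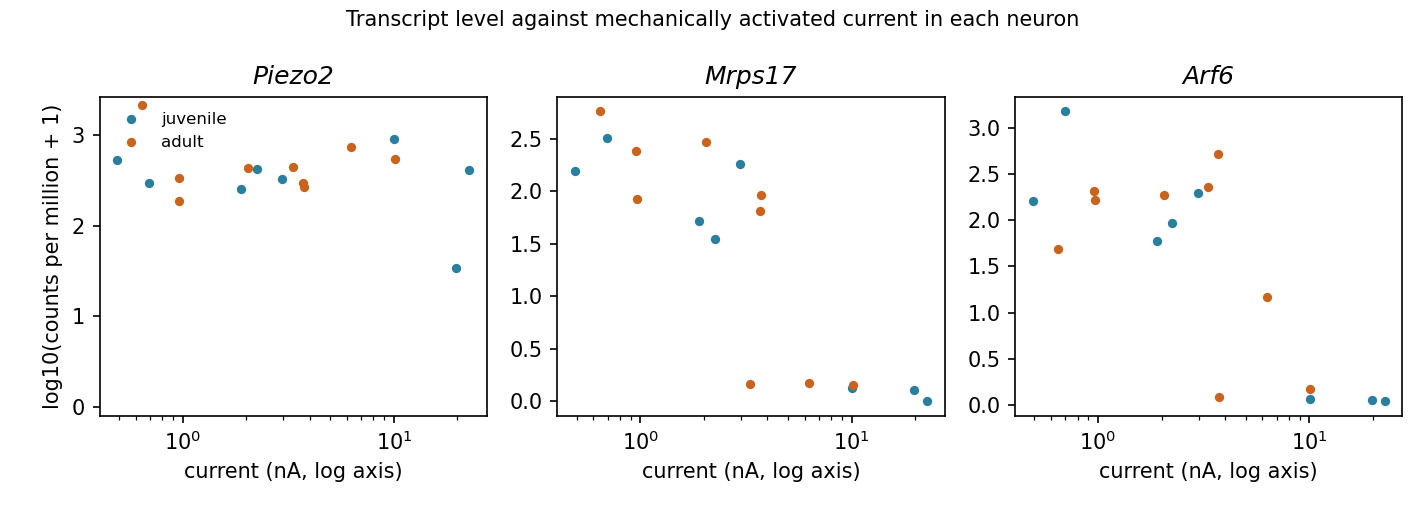
Level of Piezo2, Mrps17 and Arf6, as log10 of CPM plus 1, against the rapidly adapting current on a logarithmic axis, in each juvenile and adult neuron. Piezo2 was present across the whole range of currents, whereas Mrps17 and Arf6 were near 0 in the 3 cells of juvenile day 28 and in some adult cells.

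Depth and the number of genes detected were compared because both can move a call. Day means of the total count, in units of 1e6 counts, were 15.6 ± 5.34 in juvenile (n = 4) and 17.6 ± 2.48 in adult days (n = 5; two-sided exact permutation p = 0.460). Genes with at least 1 count numbered 8137 ± 3192 in juvenile (n = 4) and 8542 ± 743 in adult days (n = 5; two-sided exact permutation p = 0.889). At 10 CPM the order turned, with 5044 ± 2351 juvenile and 3382 ± 1099 adult genes, and this difference did not pass either (n = 4 and n = 5; two-sided exact permutation p = 0.238). Juvenile cell 2 held 8296 genes at that level and juvenile cell 8 held 1706.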

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

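Within each age, day values of the named genes on the log2(CPM + 1) scale, and depth, genes detected, mitochondrial share and current of days and cells, were searched for a single value far from the others with Dixon's test. The log2 scale was chosen after the values were seen, and the linear scale was not tried. Of 142 groups of values, 27 held one, where a rate of 1 in 20 gives 7.1. That rate assumes normally spread values. Where all other days were at 0, any count was flagged, as for Gal in juvenile day 30 and Piezo1 in adult day 85. The 7.1 is therefore no chance level for these data, and the excess over it is not a result. Several of the 27 rest on levels near 0, and no explanation was tested for them.

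Among abundant genes, Ndrg4 was lowest in adult day 85 (13.2 against 13.7 to 13.8 in the other days) and Psmc2 in juvenile day 31 (7.00 against 7.69 to 7.80). Juvenile day 31, a single cell, also had the lowest Rgs4 (0.570), Ndufs8 (0.272) and Ebp (0.272) and the highest Ubqln4 (8.10) and Kcna1 (10.7) of the juvenile days. Atp5d was highest in adult day 90 (11.8).

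Gal stood at 10.1 in adult day 102 and at 0.0221 in juvenile day 30, where the other juvenile days were at 0. Calca was 7.72 in adult day 90 and 2.88 in juvenile day 29. Pvalb (3.72), Th (1.49) and Spp1 (0.365) were also highest in juvenile day 29. In juvenile day 30 the highest values were Rgs5 at 9.51, Ntrk1 at 4.90, Sprr1a at 4.51 and Piezo1 at 0.107. In adult day 85 they were Scn3b at 5.82, Piezo1 at 5.31 and Trpc1 at 2.86. In adult day 113 they were Tmem120a at 6.22, Ebp at 1.86 and Numa1 at 0.259. Rgs5 was lowest in adult day 94 at 1.91, against 10.4 to 12.1 in the other adult days. Mitochondrially encoded genes took 3.20% of the counts in juvenile cell 6, against 0.471% to 1.71% in the other juvenile cells.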

How the results depend on the processing

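The likelihood ratio tests, the fits without juvenile cells 2 and 4, the fit without the day block, the covariate for detected genes and the limit of 10 CPM were chosen after seeing the data. The count of 0 genes between ages stayed 0 in 37 of 44 other settings, among them DESeq2 size factors, library totals, no filter, TPM values, cells as replicates and the loss of any day or cell (0 to 0). It moved to 1323 genes with DESeq2, 122 with limma voom and quality weights and 48 with the stricter filter, which depends on the ages. It was 840 with neighbouring juvenile days merged into 2 sums, and 14 with cells and the day as block. The likelihood ratio test gave 53 on day sums and 2 on cells. Among DESeq2, limma voom with quality weights, the stricter filter, the day block and the likelihood ratio test on day sums, 49 genes were called by at least 3 of the 5, all lower in adult; the day-block fit shared 0 of its 14 genes with any of the others. No label pairs the ages by cell number. Correlations between cells of the same number ran from −0.0447 to 0.0809. Of 8 numbers, 4 correlated best with their own: 5, 7, 8 and 9. How many would do so by chance was not tested. Adult cells 7, 8 and 9 also held a count for 78.2%, 90.9% and 71.2% of genes high only in the same-numbered juvenile cell. Adult cell 2 did so for 71.4% of those of juvenile cell 1. Cells of the same number can thus not be taken as unlinked. With the number as replicate block edgeR called 0 genes, as without it.

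The 3 lists became 0 with an estimated correlation, with fry, which asks only whether a list's own genes move one way, with day means of log2(CPM + 1) and without juvenile cells 2 and 4, and ranged from 0 to 9 when a day was left out: 0 without juvenile day 29 or 30 or adult day 90 or 113, 1 without adult day 85 or 102, and 9 without juvenile day 31. Lists with a median above that of all genes numbered 13, and 7 to 15 when a day was left out, 7 without juvenile day 31 and 8 without adult day 90. Genes related to current went from 70 to 428 with linear current (14 higher, 414 lower), 0 with edgeR on day sums, 0 without juvenile day 28 and 14 with the covariate for detected genes. The current difference of −0.344 ranged from −0.938 to 0.586, and was positive without juvenile day 28. The difference in genes detected was 404.5 (range −436 to 1896), but −2189 at 10 counts, −829 in thinned cells and −1662 at 10 CPM; it was −276 without juvenile day 28 and −436 without juvenile day 31, and the cause was not tested. Depth differences (in 1e6 counts) ranged from 0.278 to 3.85 and kept their sign, as did the mitochondrial share (−0.370 to −0.0857). The 59 named genes were followed only with DESeq2 size factors, DESeq2, cells as replicates, day means and each day left out. Among these settings 8 genes passed, all in DESeq2, and 7 took the other sign in at least 1. Single named genes were not followed in the other fits. At this spread 4 against 5 days can miss large differences as well as small ones. On simulated data edgeR's quasi-likelihood test recovered 28% of the genes changed 64-fold.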

Other observations

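The tests of the slope of shared low counts, of sequencing pools that follow age, and of genes at 1 to 9 counts were chosen after the result was seen.

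Mitochondrially encoded genes took 1.15 ± 0.369% of counts in juvenile (n = 4) and 0.894 ± 0.361% in adult days (n = 5; two-sided exact permutation p = 0.317).

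Adult libraries held many more genes at 1 to 9 counts than juvenile ones, 4200 ± 499 (n = 5 days) against 1607 ± 438 (n = 4 days; two-sided exact permutation p = 0.0159, the smallest this design gives), and no adult cell overlapped a juvenile one (3475 to 5163 against 984 to 2160). Of 379 genes above 100 CPM in 1 adult cell and under 10 CPM in all others, 53.0% had a count in another adult cell on average, but 8.94% in a juvenile cell. Juvenile sources differed less, with 26.4% in another juvenile cell and 16.1% in an adult cell, and sharing crossed age in single pairs picked after their values were seen. Genes of juvenile cells 7, 8 and 9 had a count in adult cells 7, 8 and 9 for 78.2%, 90.9% and 71.2% of genes, and those of juvenile cell 1 in adult cell 2 for 71.4%. The reverse shares were 5.36%, 4.55%, 6.25% and 6.67%. Gal, at 3137 CPM in adult cell 5, stood at 0.456 to 1.20 CPM in the other adult cells. The log-log slope of the other adult cells' counts on the source count was 0.840 (95% interval 0.724 to 0.948; Poisson slope 0.698). A fixed share of reads assigned to another library predicts a slope of 1 and stays open, since counts tested on simulated data in fixed proportion also gave a slope under 1. By the rule set for it, weak expression unrelated to the source count predicts no slope, and the interval argues against that form for these genes. Weak expression that follows the level in the source cell gives a positive slope too, so that form may account for the slope as well.

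In all 4 juvenile days and no adult day, 49 genes reached 10 CPM, among them Nelfb, Ubqln4, Fbxo27 and Pcdh15, and 0 genes showed the reverse. Chance was not excluded: 7 of all splits of the 9 days into 4 and 5 gave as many, with 149 as the highest of the others. Fewer genes detected in adult libraries may be enough, since simulated detection from each gene's and each cell's own rate gave 41.9 such genes (95% range 29 to 55) against 49. Sequencing pools that follow age cannot be told apart from age for these genes: genes of adult cells had low counts in other adult cells 5.93 times as often as in juvenile cells (8.94%, or 3.47% without juvenile cells 2 and 4), but the sharing from juvenile to adult cells in single pairs did not follow age, and no label gives the pools. A real loss in adult neurons stays open as well.

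The 3 lists past the camera test were set against random lists of like expression. Their medians lay at percentile 21.1 for oxidative phosphorylation, 88.5 for the proteasome list and 97.4 for the injury list. The last was barely inside its bound, but all lay within the central 95% of matched lists. A general rise of abundant genes was thus not excluded. The matched lists lay little above all tested genes, with middle medians of 0.505, 0.464 and 0.451 against 0.415. For the injury list they spread from 0.046 to 0.901, so the test cannot tell whether such a rise accounts for the lists. Chance was not excluded either, since 10 of 100 splits of the day sums gave 3 or more lists, with 5 as the highest other. For genes past the adjusted threshold in edgeR the splits decide nothing, since a count of 0 is reached by all 100 of them (highest other 3). At an unadjusted p under 0.05 in edgeR, 34 of 100 gave at least the real 154 genes (highest other 700), so chance was not excluded there. In limma voom with quality weights, 16 of 100 gave at least the real 122 genes (highest other 546), so chance was not excluded. Differences between the ages themselves stay open.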
